A study of Homo sapiens with 10 samples.

How the data were processed

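The deposited table held 49395 probe sets for 10 Affymetrix PrimeView arrays, as log2 expression values per the labels. The submitters' processing notes name RMA, the affy and limma packages and Affymetrix Expression Console. The role and order of these tools, their versions and the genome build were not given in the sources used here. The values ran from 2.32 to 14.7, and the array medians lay within 0.1 log2 units of each other, so the values were used as deposited without further scaling. Every column of the table belonged to one of the 10 arrays.

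Of the probe sets, 44994 carried 1 gene symbol, 1832 carried several and 2569 carried none. Only those with 1 symbol were kept, and 99.94% of their identifiers matched the supplied gene table. Because the debris came from donors, 26 genes (Y-linked genes, XIST and TSIX) were left out before any fit. Each of the 18106 remaining genes was represented by the probe set with the highest mean over the 10 arrays, and 11723 genes had more than 1 probe set. Genes of near-identical families, and genes read by probe sets with the suffix _x_at or _s_at, are named as uncertain where this matters, since such probe sets can bind related transcripts.

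The tests were written down before the data were examined. They were limma fits (lmFit and eBayes with default settings, limma 3.58.1 in R 4.3.3) of all 3 groups together, with 7 residual degrees of freedom and no block. P-values were adjusted by the method of Benjamini and Hochberg over all 18106 genes of a comparison, and a gene passed at an adjusted p under 0.05. Log2 changes are given with the standard error (SE) of the fit, and group means with the standard deviation (SD) between arrays. Values with no model were compared by exact 2-sided permutation tests, which cannot go below 0.0286 for 4 arrays against 3 or below 0.1 for 3 against 3.

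The 26 gene lists were also fixed beforehand. They covered placental and blood cells (syncytiotrophoblast, cytotrophoblast and extravillous trophoblast, erythroid cells, leukocytes and placental macrophages, and fibroblasts, stroma and decidua). They covered endothelial functions (endothelial identity, adhesion molecules, chemokines and cytokines, NF-kappaB targets, the interferon response, hypoxia and glycolysis, angiogenic factors, vascular tone and coagulation). They also covered metabolism and stress (cholesterol synthesis, lysosome and clearance of debris, the unfolded protein response, heat shock, NRF2 with heme and iron, metallothioneins, the cell cycle, p53 targets, the TGF-beta response, immediate early genes, oxidative phosphorylation and ribosomal proteins). Each list was tested with limma's camera at the preset inter-gene correlation of 0.01, with adjustment over the 26 lists of a comparison. Camera with a correlation estimated from the data, and fry, which asks whether the members move one way on balance, were run beside it. Neither called any list in any comparison, so every list call in this text rests on the preset correlation.

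A fit without preeclamptic debris replicate 2 (9 arrays, 6 residual degrees of freedom) and a fit without the 3 arrays of replicate number 2 (7 arrays) were added after the arrays had been compared with each other. All 3 sets of arrays were fitted for every comparison. Describing genes from the 9 arrays beside the 10, and lists from the 7 arrays, was chosen after the counts had been seen.

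Genes were named by a fixed rule. In each comparison the 12 largest rises and the 12 largest falls were named among genes that passed and whose groups did not overlap. Where fewer than 10 genes passed, the 10 genes with the smallest raw p were named as values. For each list described, the 4 members with the smallest raw p were eligible. FLT1, ENG, PGF, VEGFA, EDN1, NOS3, ICAM1, VCAM1, SELE, IL6, CXCL8, CCL2, SERPINE1 and HMOX1 were always given, except that SERPINE1 was not analysed here. Symbols that were only locus numbers or open reading frames were passed over. Genes named outside this rule were chosen after the values were seen, and the text says so.

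The titles number the replicates, and the numbers are shared by the groups, but the labels do not say what they mark. Across genes, the deviations of the untreated and normotensive debris arrays of the same number from their group means correlated at 0.532, 0.63 and 0.454, all above the limit of 0.1 set for pairing. Arrays of numbers 1 and 3 also correlated across numbers, at 0.248 and 0.374, while those of number 2 correlated with them at −0.414 to −0.538, so the numbers mainly part number 2 from 1 and 3. Genes are not independent replicates, so no p is attached to these values. The labels do not say whether the cultures were grown separately or whether preeclamptic debris replicates 1-1 and 1-2 came from one placenta, and the p-values measure only the spread between these samples.

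The alternatives included quantile normalization, centring of each array on its median, the mean of all probe sets of a gene, and all probe sets tested one by one. Others left out probe sets with the suffixes above or genes under the 40th percentile of mean expression, used eBayes with trend and robust settings, used only the arrays of the 2 groups, or used array weights. The replicate number was also fitted as a fixed and as a random block, replicates 1-1 and 1-2 were averaged, and each array was left out in turn.

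In data simulated with known changes, the fit of 10 arrays recovered 62.7% of 67 genes changed by 1 log2 unit between preeclamptic and normotensive debris, with 4 false calls. It recovered 52.2% of 67 between preeclamptic debris and untreated cells, with 10 false calls, and 49.3% of 67 between normotensive debris and untreated cells, with 10 false calls. The fit of 9 arrays recovered 89.6%, 86.6% and 80.6% of 67 in the same comparisons, with 6, 8 and 9 false calls. Changes of 0.5 log2 units were recovered for 28.8% of 66 genes at most in the first comparison, so small changes can go uncalled. The simulated values had 1 spread per gene for all groups and varied independently between genes and arrays. They held no array that stood apart and no shift shared by arrays, so these shares may differ for the real data.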

Results

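Gene expression was measured in HMEC-1 cells, an immortalised line of human microvascular endothelial cells, on 10 PrimeView arrays of 18106 genes. The cells had been kept for 21 hours with trophoblast debris, which is the cellular material that the outer layer of the placenta sheds into maternal blood. The debris was given at 60 µg/ml of protein. It came from 4 placentae of pregnancies with preeclampsia (4 arrays, replicates 1-1, 1-2, 2 and 3) or from 3 placentae of normotensive pregnancies (3 arrays), and 3 further arrays held untreated cells as the background. The labels do not say which placenta each array came from, nor whether replicates 1-1 and 1-2 share one. Each array was made from 300 ng of total RNA. Array medians lay between 6.04 and 6.14 log2 units, and the number of arrays limits the precision of every value.

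Preeclamptic debris replicate 2 stood apart from the 9 other arrays. Its correlations with them across genes were 0.871 to 0.884, while the others correlated with each other at 0.973 to 0.998. In that array 549 genes were at least 4-fold higher than the mean of the others and 997 were at least 4-fold lower. The collagen and matrix genes of fibroblasts were among the higher ones, with decorin (DCN) at 14.48 against 3.31 to 3.88, COL3A1 at 14.45 against 6.30 to 7.93 and LUM at 12.27 against 3.10 to 4.55. Endothelial receptor genes were among the lower ones, with TIE1 at 3.52 against 8.47 to 9.27, TEK at 4.55 against 9.32 to 10.63 and ECSCR at 3.05 against 10.10 to 10.92. The mean of the cell cycle list was 7.15 in that array and 10.2 to 10.4 in the others. These genes were chosen after the values were seen. The counts, the lists and the genes always given are therefore shown with and without this array.

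The untreated and normotensive debris arrays of replicate number 2 also differed together from those of numbers 1 and 3. Averaged over both arrays, all 30 endothelial identity genes were higher, by 1.18 log2 units in the mean. PECAM1, a junction molecule of endothelial cells, was at 9.97 in untreated replicate 2. The interferon response list was lower by 0.741, the chemokine and cytokine list by 0.767 and the NF-kappaB list by 0.537, while the unfolded protein response list was higher by 0.488.

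**Figure D1:**
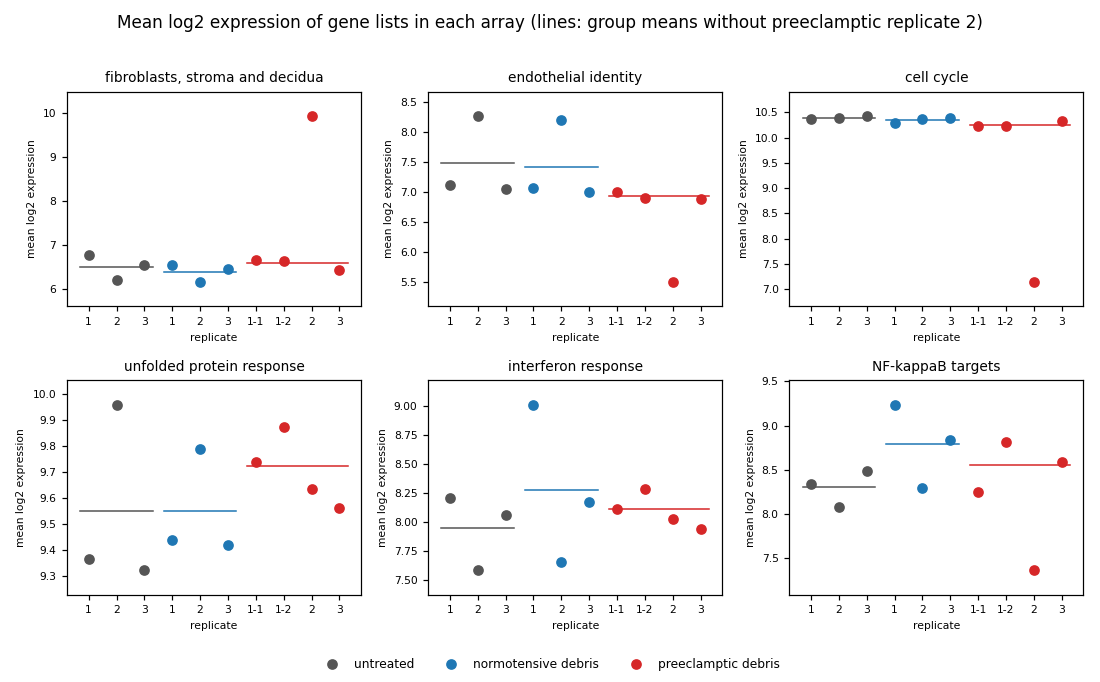
Mean log2 expression of the genes of 6 lists (vertical axes) by group (horizontal axes), 1 point per array marked by replicate number, with lines for group means without preeclamptic debris replicate 2. In that array the fibroblast list was at 9.92 against 6.17 to 6.79 in the others, and the endothelial identity list was at 5.50 against 6.88 to 8.26.

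The comparison of preeclamptic with normotensive debris asked whether endothelial cells respond differently to material from a diseased placenta. With all 10 arrays, 5 genes were lower after preeclamptic debris and 0 were higher. PDP1, whose phosphatase switches on mitochondrial pyruvate dehydrogenase, fell by 1.15 log2 units (SE 0.119) from 9.36 ± 0.189 (SD, n = 3) to 8.21 ± 0.115 (SD, n = 4). BPTF, a subunit of a chromatin remodeller, fell by 1.06 (SE 0.119), and SAMD9, an interferon-induced antiviral gene, fell by 1.24 (SE 0.145). CCDC18 fell by 1.71 (SE 0.201) and the zinc finger gene ZNF594, read by a probe set that may bind related transcripts, fell by 1.53 (SE 0.18). In preeclamptic debris replicate 2 these genes lay with the other preeclamptic debris arrays, with PDP1 at 8.22 and CCDC18 at 3.68. Their selection by a fit that holds this array leads one to expect that. Each had an adjusted p of 0.0467 and kept its direction in every alternative, but each passed in only 5 or 6 of 21 to 23 alternatives, with adjusted p up to 0.513. The raw p was under 0.05 for 1923 genes. The groups did not overlap for 2947 genes, or 16.3%, where 5.71% would be expected by chance. The next genes by raw p were JADE1, SLC35G1, RBM12, TRAK2 and TNFSF10, with changes of −1.12, −0.89, −0.85, −1.45 and −2.06 that did not pass. Leaving out preeclamptic debris replicate 3 gave 6 higher and 35 lower genes, leaving out replicate 2 gave 132 and 387, and leaving out any other array gave 0.

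Without preeclamptic debris replicate 2, the growth-control genes PTPN14 and LATS1, which restrain the growth-promoting factor YAP in the Hippo pathway, were higher after preeclamptic debris. PTPN14 rose by 1.62 log2 units (SE 0.166), 3.07-fold, from 5.16 ± 0.345 (SD, n = 3) to 6.77 ± 0.12 (SD, n = 3), with an adjusted p of 0.00593 and at most 0.0419 over its 21 alternatives. LATS1 rose by 1.41 (SE 0.155), 2.65-fold, and likewise passed in all 21 alternatives. FLCN, which adjusts mTORC1 activity at lysosomes to nutrients, rose by 1.58 (SE 0.243) and passed in 17 of 22. The clock gene PER1 rose by 1.45 (SE 0.266), the arrestin-like ARRDC3 by 1.45 (SE 0.319), PANK3, a kinase of coenzyme A synthesis, by 1.27 and the growth factor carrier IGFBP3 by 1.27. The small nucleolar RNA SNORA72, AVL9, MKRN3 and the metallothionein MT1X, whose probe set may bind its near-identical relatives, rose by 1.59, 1.37, 1.25 and 1.37. SNORA72 passed in only 12 of 21 alternatives and ARRDC3 in 10 of 22, with adjusted p up to 0.15 and 0.187. OSMR rose by 1.33 on the probe set used, with 1 of its 5 probe sets in that direction and a change of 0.01 when they were averaged.

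PCF11, which ends transcription at poly(A) sites, had one of the largest falls in the same 9 arrays. It fell by 2.59 log2 units (SE 0.313), 6.01-fold, from 7.20 ± 0.453 (SD, n = 3) to 4.61 ± 0.677 (SD, n = 3). The host transcript of microRNA 22, MIR22HG, fell by 2.40 (SE 0.255), 5.28-fold, on all 5 of its probe sets and passed in all 22 alternatives, with adjusted p up to 0.0419. The paraspeckle gene PSPC1 fell by 2.48 (SE 0.197) and the transcription factor KLF3 fell by 2.65 (SE 0.428). The probe sets read for these falls and for that of the histone acetylation factor JADE2, −1.87, may bind other transcripts. The probe set used in their place changed by 0.21 for PSPC1, 0.23 for KLF3 and 0.25 for JADE2. The genes were not settled by that, since another probe set of KLF3 was at 2.42 and another of JADE2 at −1.28, both past the threshold and neither of that kind. Translation initiation factor EIF5 fell by 2.06 on all 7 probe sets, with changes of −2.11 for the RNase gene ZC3H12C, −1.98 for the adhesion scaffold NEDD9 and −1.91 for the phosphatase subunit PPP1R10. NEDD9 passed in 9 of 22 alternatives and PPP1R10 in 11, and NEDD9 changed by −0.2711 without probe sets that may bind other transcripts (adjusted p 0.619). The ubiquitin ligase receptor BTRC, the nuclear receptor coactivator NCOA5 and FILIP1L also fell, with changes of −1.86, −1.83 and −1.82, and BTRC was likewise at −0.2617 without such probe sets (adjusted p 0.465).

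Across these 9 arrays 132 genes were higher and 387 lower, with raw p under 0.05 for 3280, and the groups did not overlap for 4860, or 26.8% against 10% expected by chance. Quantile normalization gave 203 higher and 401 lower genes. Of the 519 genes, 308, or 59.3%, had the same direction within number 2, and 65% of all genes did so. The preeclamptic debris array of that number was outside this fit but stood apart from all others. The normotensive debris array of that number was inside the fit, which favours agreement. The share therefore neither bears out nor refutes the 519 calls. Within numbers 1 and 3 all 519 genes agreed, as their selection from these arrays leads one to expect, and 79.4% and 74.8% of all genes agreed there. Of the 519 genes, 352 also passed with numbers 1 and 3 only. In preeclamptic debris replicate 2 itself, LATS1 (4.27), FLCN (6.93), KLF3 (8.59) and MIR22HG (10.42) did not share the change and were at or beyond the levels of the other groups. PTPN14 (5.60) lay just above their highest value of 5.53, and PCF11 (5.93) was lower than in them. Each further array mattered to the counts. Leaving out preeclamptic debris replicates 1-1, 1-2 or 3 gave 5 and 17, 4 and 20, or 259 and 793 higher and lower genes. Leaving out normotensive debris replicates 1, 2 or 3 gave 76 and 267, 9 and 30, or 4 and 16. Leaving out untreated replicates 1, 2 or 3 gave 48 and 195, 265 and 644, or 39 and 171. Averaging replicates 1-1 and 1-2 left 5 higher and 18 lower genes.

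**Figure D2:**
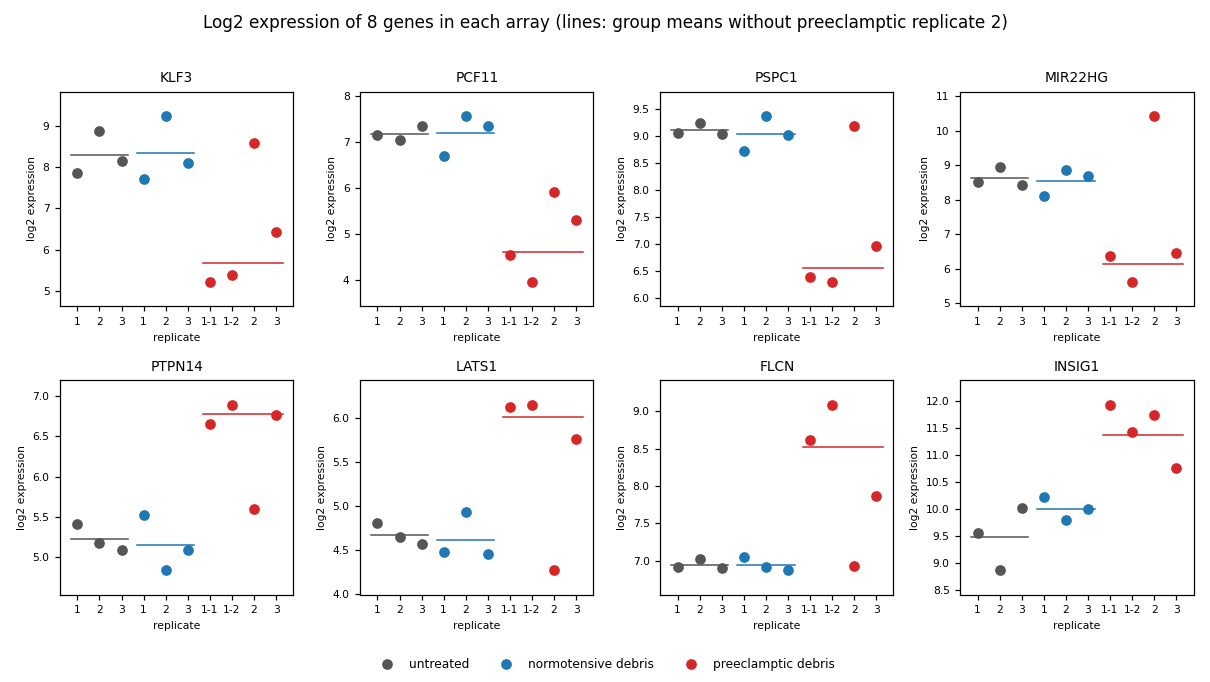
Log2 expression of 8 genes (vertical axes) by group (horizontal axes), 1 point per array marked by replicate number, with lines for group means without preeclamptic debris replicate 2. PTPN14 had a mean of 6.77 with preeclamptic debris against 5.16 with normotensive debris and 5.23 in untreated cells, and PCF11 had means of 4.61, 7.20 and 7.19.

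Of the 26 gene lists tested between preeclamptic and normotensive debris in 10 arrays, 2 were higher, 4 were lower and 20 did not pass, the latter with medians from −0.338 to 0.81. The cell cycle list was lower (median −0.81, 1 of 44 genes positive, adjusted p 7.41e-08, range over alternatives 2.22e-10 to 0.132), with PCNA, the DNA polymerase clamp, at −0.74 (SE 0.387). Endothelial identity was lower (median −0.863, 4 of 30 positive, adjusted p 4.14e-05, range 2.4e-07 to 0.268), with the endothelial transcription factor ERG at −2.21 (SE 0.854). NF-kappaB targets were lower (median −0.361, 6 of 26 positive, adjusted p 6.84e-04, range 9.52e-10 to 0.128), and so was the interferon response (median −0.181, 14 of 44 positive, adjusted p 0.00279, range 2.85e-11 to 0.791). Genes of the syncytiotrophoblast were higher (median 0.238, 34 of 37 positive, adjusted p 0.00118, range 3.59e-04 to 0.116), with the inhibin gene INHA at 0.49 (SE 0.133), and genes of leukocytes and placental macrophages were higher (median 0.162, 21 of 24 positive, adjusted p 0.032, range 0.0211 to 0.33). Apart from SAMD9 in the interferon list, 0 members of these lists passed, also when adjusted over the list alone. The adjusted p with an estimated correlation was 0.763 for each of these 6 lists. Preeclamptic debris replicate 2 carried much of this. Its cell cycle mean was 7.15, against 10.22 to 10.33 in the other preeclamptic debris arrays and 10.28 to 10.39 with normotensive debris. Nearly all of the cell cycle fall therefore lay in that array. Its NF-kappaB mean was 7.37, against 8.25 to 8.81 and 8.29 to 9.24 in the same arrays. Without this array the lists other than endothelial identity had adjusted p from 0.102 to 0.128. Without normotensive debris replicate 1 the adjusted p was 0.102 for leukocytes, 0.102 for NF-kappaB and 0.791 for interferon, and without normotensive debris replicate 2 it was 0.0535 for endothelial identity. Median, mean and test differed in sign for adhesion molecules, hypoxia, angiogenic factors, p53 targets and the TGF-beta response, none of which passed.

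Only endothelial identity passed between the debris groups in the 9 arrays, with 0 lists higher, 1 lower and 25 not passing. Its median was −0.427 with 4 of 30 genes positive and an adjusted p of 0.0151 (range over alternatives 5.18e-05 to 0.636), and 0.769 with an estimated correlation. ERG was at −1.34 (SE 0.402) and ENG, the TGF-beta co-receptor endoglin, at −1.19 (SE 0.413), and 0 of the 30 members passed over all genes or adjusted over the list alone. The high values of normotensive debris replicate 2 bore on this call, since without that array the median was −0.0229 and the adjusted p 0.636, and without preeclamptic debris replicate 3 it was 0.0609. With the replicate number as a block this call was lost as well. The interferon, NF-kappaB, chemokine and unfolded protein response lists passed instead, as given under the processing. Signs differed between median, mean and test for adhesion molecules, chemokines, vascular tone and the TGF-beta response here, and for adhesion molecules and angiogenic factors in the 7 arrays.

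With the arrays of numbers 1 and 3 only, several inflammatory genes were lower after preeclamptic than after normotensive debris. CXCL1 and CXCL2, chemokines that attract neutrophils, fell by 2.11 (SE 0.347) and 1.60 (SE 0.309), and the monocyte chemokine CCL2 fell by 1.98 (SE 0.401, n = 3 against 2). The kinase gene MAP3K8 fell by 1.43 (SE 0.137) and TNFAIP2 by 1.14 (SE 0.127). Among antiviral genes IFIT3 and PARP9 each fell by 1.30 (SE 0.16 and 0.162) and IFIT2 by 0.89 (SE 0.154). The NF-kappaB list was lower (adjusted p 2.65e-05, 4 of 26 members lower, 9 when adjusted over the list alone), as were the interferon list (5.34e-08, 8 of 44, 11 over the list alone) and the chemokine list (0.0148, 3 of 28, 6 over the list alone). The interferon and chemokine calls rested on normotensive debris replicate 1, without which the adjusted p was 0.217 and 0.456. The chemokine list was also lost without preeclamptic debris replicates 1-1 (0.054) or 3 (0.174). NF-kappaB stayed past the threshold under each removal, with adjusted p up to 0.0187, but its median shrank from −0.254 to −0.0593 without normotensive debris replicate 1. Normotensive debris replicate 2, left out here, had an interferon mean of 7.656, below the 7.935 to 8.286 of the preeclamptic debris arrays. Its NF-kappaB mean of 8.293 lay within the 8.25 to 8.813 of the preeclamptic debris arrays of numbers 1 and 3. Its chemokine mean of 6.756 lay below their 6.842 to 7.412. Untreated replicate 2 was also below the other untreated arrays in the interferon, NF-kappaB and chemokine lists, at 7.585, 8.084 and 6.307. In the 9 arrays the interferon, NF-kappaB and chemokine lists had not passed (adjusted p 0.102, 0.128 and 0.36). In numbers 1 and 3 the unfolded protein response, by which cells relieve a stressed endoplasmic reticulum, was higher (median 0.225, adjusted p 0.0011, 4 of 34 members higher, 12 over the list alone). It held under each removal of 1 of these 7 arrays, with adjusted p from 3.86e-05 to 0.011. Its members PSAT1, VLDLR, HERPUD1 and MTHFD2 rose by 0.97 (SE 0.182), 0.83 (SE 0.176), 1.15 (SE 0.244) and 0.52 (SE 0.111). The arrays of number 2, left out here, ran the other way. Their list means were 9.632 with preeclamptic debris, 9.787 with normotensive debris and 9.958 in untreated cells. In the 10 and the 9 arrays the list had not passed (adjusted p 0.586 and 0.141). In these 7 arrays 1 list was higher, 3 were lower and 22 did not pass, the adjusted p with an estimated correlation was 0.671 for each of the 4, and 181 genes were higher and 388 lower. The gene calls depended on single arrays, with 8 and 12 left without normotensive debris replicate 1, 0 and 0 without 3, 7 and 12 without preeclamptic debris replicate 1-1, 18 and 49 without 1-2, 757 and 1471 without 3, and 14 and 43 without untreated replicate 1 or 3.

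The genes long tied to preeclampsia and endothelial activation did not pass between the debris groups in 10 arrays, where the lowest adjusted p among them was 0.435 for CCL2. The VEGF receptor gene FLT1 changed by −0.67, ENG by −0.80, PGF by −0.35 and VEGFA by 0.18. The vasoconstrictor gene EDN1 changed by −1.54 and the nitric oxide synthase gene NOS3 by 0.12. Among adhesion molecules and cytokines, ICAM1 changed by −0.58, VCAM1 by −1.86, SELE by 0.29, IL6 by −1.33, CXCL8 by −2.32 and CCL2 by −1.86. HMOX1, which breaks down heme, changed by 1.02, and SERPINE1 was not analysed here. Several of these values rested on preeclamptic debris replicate 2, where HMOX1 was at 10.88, CXCL8 at 4.84 and VCAM1 at 3.62. Without it HMOX1 changed by 0.28, CXCL8 by −0.365, VCAM1 by −0.68, ICAM1 by 0.22, SELE by 0.23, IL6 by −1.35 and CCL2 by −1.415, and none passed. FLT1, ENG, PGF, VEGFA, EDN1 and NOS3 changed by −0.22, −1.19, −0.24, 0.23, −1.44 and 0.05 in those 9 arrays, likewise without passing. With numbers 1 and 3 only, ENG fell by 0.80 (adjusted p 0.0431) and EDN1 fell by 0.68 (0.0452), while FLT1 and PGF turned to 0.28 and 0.04. This setting is itself among the alternatives to the 10 arrays. Over those the adjusted p ranged from 0.0224 to 0.828 for ENG and from 0.0452 to 0.809 for EDN1, whose lowest value came from this setting.

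The comparison of preeclamptic debris with untreated cells asked what the material does to a resting endothelium. With all 10 arrays, 5 genes were lower and 0 higher, 4 of them the same as between the debris groups. BPTF fell by 1.14 (SE 0.119) from 8.36 ± 0.0486 (SD, n = 3) to 7.23 ± 0.147 (SD, n = 4) and PDP1 fell by 1.13 (SE 0.119), with adjusted p of 0.0463. ZNF594 fell by 1.56, CCDC18 by 1.72 and JADE1, which guides histone acetylation, by 1.25 (SE 0.148). They passed in 6 to 9 of 21 to 23 alternatives with no change of direction, and the adjusted p rose to 0.341 at most. The raw p was under 0.05 for 3054 genes, and the groups did not overlap for 3827, or 21.1% against 5.71% by chance. RNPC3, FERRY3, SAMD9, TRAK2 and IKZF2 followed by raw p, with changes of −0.94, −1.42, −1.07, −1.50 and −1.09 that did not pass, the last on 1 of 3 probe sets. Leaving out preeclamptic debris replicate 3 gave 13 higher and 83 lower genes, leaving out replicate 2 gave 211 and 823, and leaving out any other array gave 0.

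The sterol sensor gene INSIG1 showed the largest rise over untreated cells among the genes that passed in the 9 arrays, 1.90 log2 units (SE 0.321) or 3.72-fold, from 9.49 ± 0.574 (SD, n = 3) to 11.38 ± 0.59 (SD, n = 3). Its adjusted p was 0.0147 and at most 0.0763 over 22 alternatives. The rise was larger in preeclamptic debris replicates 1-1 and 1-2, at 11.94 and 11.44 against 9.56 in untreated replicate 1. In number 3 it was at 10.76 against 10.02. INSIG1 was also high, at 11.75, in preeclamptic debris replicate 2, but that array stood apart from all others. Of the other cholesterol genes, which did not pass as a list, MSMO1 rose by 1.04 (SE 0.184) and HMGCS1 by 1.02 (SE 0.24). In preeclamptic debris replicate 2 HMGCS1 was at 7.81, within the 7.22 to 8.09 of untreated cells. PTPN14 rose by 1.55 and LATS1 by 1.35, 2.92-fold and 2.54-fold, and both passed in all 21 alternatives. FLCN, SNORA72, ARRDC3, PER1, PANK3 and AVL9 rose by 1.58, 1.59, 1.58, 1.52, 1.48 and 1.36, close to their changes against normotensive debris. The long noncoding RNA LINC00839 and the tight junction gene CLDN14 rose by 1.54 and 1.52. They passed in only 11 and 10 of 21 alternatives, with adjusted p up to 0.157 and 0.108. The metallothionein MT1X, uncertain for the reason given, rose by 1.58.

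The toll-like receptor gene TLR4, which senses bacterial lipid and damaged tissue, fell by 2.58 (SE 0.57), 5.97-fold, from 8.80 ± 1.06 (SD, n = 3) to 6.22 ± 0.531 (SD, n = 3), and passed in 13 of 22 alternatives with adjusted p up to 0.141. PCF11 and MIR22HG changed by −2.58 and −2.49 and passed in all 22 alternatives, as did NCOA5 and the translational repressor NANOS1 with changes of −1.99 and −1.91. KLF3, PSPC1 and JADE2 fell on the probe sets used, with changes of −2.59, −2.55 and −1.92, and the probe sets used in place of those that may bind other transcripts changed by 0.20, 0.05 and 0.30. Here too another probe set of KLF3 was at 2.49 and another of JADE2 at −1.23, both past the threshold. EIF5, BTRC, PPP1R10 and FILIP1L fell, with changes of −2.07, −1.93, −1.90 and −1.89, although BTRC was at −0.2455 without probe sets that may bind other transcripts (adjusted p 0.391) and PPP1R10 passed in 13 of 22 alternatives. Of the immediate early genes, which did not pass as a list, FOSL2 was at −1.45 (SE 0.262) and MYC at −1.33 (SE 0.256), while MAFF, a small partner of NRF2, rose by 0.96 (SE 0.143).

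Against untreated cells 211 genes were higher and 823 lower in the 9 arrays, so that 20.4% of the calls were higher, and the share was 31.8% after quantile normalization (305 higher, 655 lower) and 28.6% after centring (250 and 624). The groups did not overlap for 6090 genes, or 33.6% against 10% by chance. Of these 1034 genes, 653 or 63.2% had the same direction within number 2, against 68% of all genes. Here too the share is no independent check, since untreated replicate 2 was inside the fit and preeclamptic debris replicate 2 stood apart. Of the 1034 genes, 708 also passed with numbers 1 and 3 only. Leaving out preeclamptic debris replicates 1-1 or 1-2 gave 10 and 53 or 13 and 70 higher and lower genes. Leaving out untreated replicates 1, 2 or 3 gave 44 and 256, 91 and 275, or 46 and 288, and leaving out normotensive debris replicates 1 or 3 gave 137 and 637 or 82 and 392. Averaging replicates 1-1 and 1-2 left 12 and 71. Of the 519 genes called between the debris groups, 464 were called in the same direction here, 97 higher and 367 lower, where 1.54 and 17.6 would be shared if the calls were independent. The comparisons share the preeclamptic debris arrays, which by itself raises this number.

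Among the 26 lists against untreated cells in 10 arrays, 3 were higher, 2 lower and 21 did not pass, with medians from −0.106 to 0.779. Genes of the syncytiotrophoblast were higher (median 0.317, 36 of 37 positive, adjusted p 2.47e-04, range over alternatives 3.07e-05 to 0.0617), as were those of erythroid cells (median 0.243, adjusted p 0.0381, range 0.025 to 0.195) and of leukocytes and placental macrophages (median 0.193, adjusted p 0.0381, range 0.0187 to 0.197). Endothelial identity was lower (median −1.02, adjusted p 2.28e-04, range 1.01e-05 to 0.0741) and so was the cell cycle (median −0.838, adjusted p 8.91e-07, range 4.99e-09 to 0.0281). Nearly all of the cell cycle fall lay in preeclamptic debris replicate 2, with a mean of 7.15. The other preeclamptic debris arrays were at 10.22 to 10.33 and untreated cells at 10.36 to 10.42. The adjusted p with an estimated correlation was 0.931 for each of the 5, and 0 of their members passed, against 1 syncytiotrophoblast and 1 erythroid gene when adjusted over the list alone. The erythroid call was lost without untreated replicate 2 (0.0772), preeclamptic debris replicate 2 (0.056) or 3 (0.0721), with quantile normalization (0.18), with the mean of all probe sets (0.0821) and without dim genes (0.195). The leukocyte call was lost without preeclamptic debris replicate 1-1 (0.0539) or 2 (0.056) or untreated replicate 2 (0.0896), with quantile normalization (0.197) and without dim genes (0.178), and the endothelial call without untreated replicate 2 (0.0601). The syncytiotrophoblast, erythroid and leukocyte lists had means of 4.55 to 5.51 per array, below the array medians, and the interquartile range was 3.46 to 3.85 in the preeclamptic debris arrays and 3.84 to 4.12 in the others. The signs of median, mean and test differed for NF-kappaB targets, interferon, angiogenic factors, p53 targets, the TGF-beta response and ribosomal proteins, and in the 7 arrays for interferon and coagulation.

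Of the lists, 1 was higher than in untreated cells in the 9 arrays, 2 were lower and 23 did not pass. Syncytiotrophoblast genes were higher by a median of 0.169 (adjusted p 0.0121, range 0.00334 to 0.164), and INHA, the only member to pass over all genes and over the list alone, rose by 0.63 (SE 0.125). The cell cycle list was lower by a median of 0.107 (adjusted p 0.0281, range 0.0067 to 0.2), where the mitotic motor genes KIF11 and CENPE and the kinetochore gene CENPF fell by 0.73 (SE 0.124), 0.48 (SE 0.11) and 0.72 (SE 0.14), and 4 of 44 members passed when adjusted over the list alone. Endothelial identity was lower by a median of 0.445 (adjusted p 0.0121, range 3.95e-04 to 0.399) with 0 members past. The adjusted p with an estimated correlation was 0.736 for each. Untreated replicate 2 bore on the calls, since without it the adjusted p was 0.0934 for syncytiotrophoblast and 0.399 for endothelial identity. Its endothelial mean was 8.26, against 7.05 and 7.11 in the other untreated arrays and 6.88 to 6.99 with preeclamptic debris. Much of the endothelial change therefore lay in that array. Without preeclamptic debris replicate 1-2 the adjusted p was 0.0607 for the cell cycle. With the replicate number as a block the unfolded protein response and NRF2 lists passed, as given under the processing.

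Single genes also passed in lists that did not. Cholesterol synthesis (27 genes, median 0.0731, adjusted p 0.171) had 3 higher genes and 4 when adjusted over the list alone. The unfolded protein response (34, median 0.208, adjusted p 0.056) had 2 higher, MANF by 0.43 (SE 0.105) and HERPUD1 by 1.01 (SE 0.249), and 2 over the list alone. Metallothioneins (13, median 0.785, adjusted p 0.056) had 2 higher, both with near-identical relatives. Erythroid genes (11, median 0.189, adjusted p 0.056) had the globin gene HBB higher by 0.42 (SE 0.104) and 2 over the list alone. In p53 targets (28, median −0.0751, adjusted p 0.433) the p53 ligase gene MDM2 fell by 0.66 (SE 0.149) and the DNA repair gene XPC by 0.74 (SE 0.174), 4 over the list alone. Immediate early genes (28, median −0.0678, adjusted p 0.433) had 1 higher and 2 lower, with 3 and 6 over the list alone. The interferon response (44, median 0.246, adjusted p 0.583) had SAMD9 and PARP9 lower by 1.04 and 0.88, heat shock genes (23, median 0.04, adjusted p 0.508) had DNAJB1 lower by 0.51, and the TGF-beta response (34, median −0.0236, adjusted p 0.508) had ID1 lower by 1.35. Angiogenic factors (37, median 0.0745, mean −0.0155, adjusted p 0.628) had HBEGF lower by 0.77.

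The remaining lists had 0 members past the threshold against untreated cells in the 9 arrays. Placental lists were positive in the median without passing, with cytotrophoblast and extravillous trophoblast at 0.172 (adjusted p 0.0643), leukocytes and placental macrophages at 0.143 (0.056) and fibroblasts, stroma and decidua at 0.0757 (0.985). Of the endothelial lists, adhesion molecules were at 0.125 (0.508), chemokines and cytokines at 0.273 (0.056), NF-kappaB targets at 0.269 (0.0685), vascular tone at 0.146 with a mean of −0.0288 (0.474) and coagulation at 0.153 (0.433). Of the metabolic lists, hypoxia and glycolysis was at 0.268 (0.056), lysosome and clearance of debris at −0.0447 (0.985), NRF2 with heme and iron at 0.0993 (0.221), oxidative phosphorylation at 0.0592 (0.508) and ribosomal proteins at 0.0579 (0.349).

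With numbers 1 and 3 only, the unfolded protein response was higher than in untreated cells (median 0.338, 31 of 34 genes positive, adjusted p 8.3e-06, 0.824 with an estimated correlation). Its regulators XBP1 and DDIT3 rose by 0.56 (SE 0.0913) and 0.64 (SE 0.113), the phosphatase subunit PPP1R15A by 0.98 (SE 0.185) and HERPUD1 by 1.19 (SE 0.244). Of its members 7 passed, and 13 when adjusted over the list alone. The call held under each removal of 1 of these 7 arrays, with adjusted p from 2.16e-07 to 1.93e-05. Untreated replicate 2, left out here, had a list mean of 9.958, above the 9.561 to 9.87 of the preeclamptic debris arrays. In the 10 and the 9 arrays the list had not passed (adjusted p 0.507 and 0.056). In numbers 1 and 3 NRF2 targets were higher (median 0.161, adjusted p 0.0386, 0.824 estimated), with 3 of 31 members past by either adjustment, namely SQSTM1 by 0.57 (SE 0.108), NQO1 by 0.51 (SE 0.112) and OSGIN1 by 0.35 (SE 0.0802). The cell cycle list was lower (median −0.0909, adjusted p 0.0275, 0.824 estimated, 3 members lower by either adjustment). The NRF2 call was lost without preeclamptic debris replicate 3 (0.0968) or untreated replicate 1 (0.14), and the cell cycle call without preeclamptic debris replicate 1-2 (0.0574) or untreated replicate 3 (0.076). Here 2 lists were higher, 1 was lower and 23 did not pass, and 247 genes were higher and 740 lower. Without untreated replicate 1 or 3 the gene calls became 0 and 0, without normotensive debris replicate 1 or 3 they were 143 and 436, and without preeclamptic debris replicates 1-1, 1-2 or 3 they were 23 and 87, 42 and 139, or 926 and 1858.

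Of the preeclampsia and activation genes, none passed against untreated cells in 10 arrays, and the lowest adjusted p was 0.234 for SELE (range over alternatives 0.0384 to 0.608). FLT1 changed by −0.91, ENG by −0.88, PGF by −0.36, VEGFA by 0.21, EDN1 by −1.71 and NOS3 by 0.18. ICAM1 changed by 0.15, VCAM1 by −1.48, SELE by 0.40, IL6 by 0.01, CXCL8 by −1.16, CCL2 by −0.46 and HMOX1 by 1.08. Preeclamptic debris replicate 2 carried much of this, and without it HMOX1 changed by 0.34, VCAM1 by −0.30, CXCL8 by 0.80, ICAM1 by 0.96, SELE by 0.34, IL6 by −0.0052 and CCL2 by −0.0077. FLT1, ENG, PGF, VEGFA, EDN1 and NOS3 changed by −0.47, −1.28, −0.26, 0.26, −1.61 and 0.11 there, and none of the 13 genes passed. With numbers 1 and 3 only, ENG fell by 0.81 (adjusted p 0.0317) and EDN1 by 0.88 (0.0197), while FLT1, PGF and CXCL8 turned to 0.02, 0.14 and 0.56. Over the alternatives to the 10 arrays, which hold this setting, the adjusted p ranged from 0.0232 to 0.753 for ENG. For EDN1 it ranged from 0.0197, the value of this setting, to 0.654.

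The comparison of normotensive debris with untreated cells asked what debris of an uncomplicated pregnancy does by itself. Inflammatory lists were higher by camera at the preset correlation, although limma called 0 genes in 10 arrays with raw p under 0.05 for 90 genes. That was 0.497% of genes, a smaller share than a threshold of 0.05 gives when nothing changes. The 0 calls therefore do not show that normotensive debris had no effect. The interleukins IL1A and IL6 changed by 0.79 (SE 0.324) and 1.35 (SE 0.642), the chemokines CXCL6 and CCL2 by 1.77 (SE 0.941) and 1.41 (SE 0.759), and the NF-kappaB subunit gene NFKB1 by 0.47 (SE 0.243), with n = 3 in each group. All 26 NF-kappaB targets were positive (median 0.38, adjusted p 1.23e-11, range over alternatives 3.83e-28 to 2.7e-04, 0.715 with an estimated correlation). Of the chemokines and cytokines 25 of 28 were positive (median 0.566, adjusted p 7.32e-09, range 7.07e-17 to 0.00174, 0.715 estimated). Of the interferon response 43 of 44 were positive (median 0.256, adjusted p 3.57e-10, range 2.32e-26 to 0.975, 0.928 estimated), with the antiviral gene OAS1 at 0.61 (SE 0.416). The interferon call rested on normotensive debris replicate 1, without which the median was −0.0519 and the adjusted p 0.975. Exact permutation tests of the list means gave p of 0.3 for NF-kappaB, 0.3 for chemokines and 0.5 for interferon (adjusted p 0.904 each). With 3 arrays against 3 such a test cannot go below 0.1, so it could not call a list here, and it left out the pairing by number. In these lists 0 members passed over all genes or when adjusted over the list alone, 3 lists were higher and 23 did not pass, with medians from −0.103 to 0.135. The groups did not overlap for 1112 genes, or 6.14% against 10% by chance, a share that like the SE values leaves out the pairing by number. Within numbers 1, 2 and 3 CCL2 differed by 2.05, 1.42 and 0.751, and the NF-kappaB mean was 9.24 against 8.34, 8.29 against 8.08 and 8.84 against 8.49, but with the number as a block 0 genes passed as well. Signs of median, mean and test differed for coagulation, the unfolded protein response and oxidative phosphorylation in the 10 and the 9 arrays, and for syncytiotrophoblast, leukocytes and ribosomal proteins in the 7.

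By raw p the leading genes after normotensive debris were TMEM217 (0.59), the collagen gene COL8A1 (−0.52), RNASE8 (0.38), LINC01602 (0.37), the adhesion receptor ADGRG2 (0.35), INTS6L (−0.51), PPIL6 (0.40, 1 of 3 probe sets), WNT2B (−0.53), OR1N2 (0.35) and NTF4 (−0.57), each with an adjusted p of 1. Of the genes always given, ICAM1 changed by 0.74, VCAM1 by 0.37, SELE by 0.11 and CXCL8 by 1.16. FLT1, ENG, PGF, VEGFA, EDN1, NOS3 and HMOX1 changed by −0.25, −0.09, −0.02, 0.03, −0.17, 0.06 and 0.06. The spread estimated from the 9 or the 7 arrays also gave 0 calls, with raw p under 0.05 for 328 and 466 genes. These were 1.81% and 2.57% of genes, again less than a threshold of 0.05 gives when nothing changes. Erythroid genes were higher as well in the 9 arrays (median 0.11, adjusted p 0.0448), with an adjusted p of 0.767 by estimated correlation for each of the called lists, 4 lists higher and 22 not passing, and with the replicate number as a block the adjusted p was 0.0505 for that list and 0.0328 for fibroblasts, stroma and decidua (0.12 without block). The erythroid call was lost without normotensive debris replicate 1 (0.209), untreated replicate 2 (0.378) or preeclamptic debris replicate 3 (0.054), and the interferon call again without normotensive debris replicate 1 (0.966).

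With numbers 1 and 3 only, the 3 inflammatory lists were again higher, NF-kappaB by a median of 0.537, chemokines by 0.749 and interferon by 0.412, and 12, 6 and 0 of their members were higher when adjusted over the list alone. Also called were the unfolded protein response (median 0.0828, adjusted p 0.00864) and p53 targets (0.095, 6.08e-04), both higher, and fibroblasts, stroma and decidua (−0.149, 0.0124), which was lower. Without normotensive debris replicate 1 the interferon list was lost (0.111), and the medians shrank to 0.256 for chemokines and 0.398 for NF-kappaB. Without normotensive debris replicate 3 the unfolded protein, p53 and fibroblast calls were lost (0.0557 each), as was the first without untreated replicate 3 (0.0701) and the last without untreated replicate 1 (0.396). The adjusted p with an estimated correlation was 0.397 to 0.683 for these 6 lists, with 5 lists higher, 1 lower and 20 not passing.

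The effects of both kinds of debris were compared through the untreated arrays they share. Normotensive debris gave 0 calls, so no gene could be called in both comparisons with untreated cells, and the overlap of 0 carries no information. Across genes, the changes by preeclamptic and normotensive debris had a covariance of 0.019 in 10 arrays, against 0.0639 in 100 simulated draws of unchanged groups with shared untreated arrays. In the 9 arrays the covariance was 0.0197 against 0.0163, and 68.4% of genes changed in the same direction against 66.7% simulated, but the correlation of 0.436 lay below the simulated 0.499. The draws used the spread pooled over the groups, which in 10 arrays holds that of preeclamptic debris replicate 2, and left out the pairing by number, so these differences decide nothing about a shared effect. Relative to untreated cells in numbers 1 and 3, CCL2 was at −0.58 with preeclamptic debris and at 1.40 with normotensive debris, whereas CXCL8 (0.56 and 1.20) and ICAM1 (0.57 and 0.77) were positive with both, and none of these passed. The NF-kappaB and chemokine lists were also positive with preeclamptic debris there, with medians of 0.206 and 0.196 that did not pass.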

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

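The tests of what set preeclamptic debris replicate 2 and the arrays of number 2 apart, and those of the opposing probe sets, were chosen only after the result was seen, while the regroupings of the samples were written down beforehand for the 10 arrays.

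A value was listed as far from its group by Dixon's ratio for the 4 preeclamptic debris arrays, against a critical value that about 1 in 20 groups with no real outlier would pass. Among 76 genes tested, 10 were listed. SLC35G1 (0.87) stood out in replicate 1-1, and the others stood out in replicate 2, namely CXCL8 (0.86), CD68 (0.9), ROBO4 (0.89), PCNA (0.93), CDC45 (0.89), KIF11 (0.93), CENPF (0.93), EGFL7 (0.93) and MCM6 (0.88). Among the 26 list means, 8 were listed, all in replicate 2. They were fibroblasts, stroma and decidua (0.94), endothelial identity (0.93), vascular tone (0.9), lysosome and clearance of debris (0.92), NRF2 with heme and iron (0.93), the cell cycle (0.96), the TGF-beta response (0.84) and ribosomal proteins (0.84). Of the 8 array measures, the median correlation with the other arrays (0.93) and the hybridisation control mean (0.86) were listed, again in replicate 2. These items are not independent, since many of the genes were members of lists called in the 10 arrays and share those lists with the means. Their concentration in 1 array was not tested against chance.

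The first pattern was preeclamptic debris replicate 2 itself. Trophoblast RNA carried over with the debris was tested by the syncytiotrophoblast genes, whose median rise of 0.596 in that array was far below the 2.81 of the fibroblast genes, so it does not account for the pattern. Degraded RNA was not borne out either, since the ACTB 3' minus 5' difference was 0.634 against up to 0.811 in the others, and a response of the whole preeclamptic debris group was not seen, since the fibroblast list differed by 0.13 in the 3 other arrays of the group and by 3.47 in this one. RNA of cells other than the endothelial line remains open. In that array 21 of 30 endothelial genes were lower than in all 9 others and 15 of 17 fibroblast genes higher. These counts restate what set the array apart and cannot bear it out. Of 44 cell cycle genes 42 were lower than in all 9 others and 1 was higher, with a median difference of −2.95. The endothelial median was −1.39, with 3 genes higher than in all others. Falls of this size argue against a small share of other RNA added to that of the line. The endothelial and cell cycle calls of fits that hold this array are therefore not shown to be an effect of debris.

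The second pattern was the shift shared by the untreated and normotensive debris arrays of number 2. The endothelial list shifted by 1.18 there, where the highest of 10000 random lists of like expression shifted by 0.262. The list was tested after its shift had been seen, and its 30 genes moved together, unlike genes drawn at random. The test therefore cannot exclude RNA input or labelling. The poly-A spikes (8.83 and 8.63) and the 18S signal (13.07 and 12.7) were also higher in these arrays than in numbers 1 and 3 of their groups (6.65 to 7.26 and 10.48 to 11.53). Preeclamptic debris replicate 2 shared this, with 9.86 and 12.48, so all 3 arrays of number 2 stood apart in these signals and a difference in RNA input remains open. A culture or batch shared by these arrays remains open, because the correlation of 0.63 between their deviations is the pattern itself and the labels name no batch.

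The third pattern was probe sets of 1 gene that moved oppositely with preeclamptic debris in the 9 arrays, which was seen for 63 genes against untreated cells and 37 against normotensive debris. ABL2 had probe sets at −1.03 and 1.18 against normotensive debris, and KLF3 at −2.65 and 2.42, the former on a probe set that may bind other transcripts. Degraded RNA could contribute, since the ACTB 3' minus 5' difference was 0.76 with preeclamptic debris and 0.563 in the other groups, and the exact permutation p was 0.0714 for ACTB and 0.0238 for GAPDH, whose difference was only 0.0273, so this cannot be decided. Probe sets that bind other transcripts do not account for the whole pattern, since 42 of the 63 genes remained without them, but they are not excluded for the others, KLF3 included.

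The samples were regrouped in every way to see how often chance gives as many calls. Between the debris groups in 10 arrays, 2 of 35 splits gave as many genes as the real 5, and the highest other gave 12. Against untreated cells 3 of 35 did, and the highest other gave 47. Neither count therefore excludes chance. The splits with 12 and 47 calls point to a structure of the samples, namely the debris grouping with 1 array moved, since they set preeclamptic debris replicate 3 with normotensive debris and preeclamptic debris replicate 2 with untreated cells. In the 9 arrays the real split was the only 1 of 10 to reach 519 and 1034 genes, and the highest other gave 0, but 10 splits are too few for a share under 0.05. Between normotensive debris and untreated cells all 10 of 10 splits gave 0.

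The lists fared worse under regrouping. Between the debris groups in 10 arrays, 32 of 35 splits called as many lists as the real 6, and the highest other called 14. Against untreated cells 35 of 35 called as many as the real 5, with up to 14. Between normotensive debris and untreated cells, which pair by number, 7 of 10 called as many as the real 3, with up to 13. The highest counts, 7 to 13, came from splits that part only number 1 or only number 3 and keep the 2 arrays of number 2 together, so they carry the shift of number 2, while the 3 other splits that part all 3 numbers called 4, 3 and 1. In the 9 arrays 10 of 10 and 9 of 10 splits called as many as the real 1 and 3, with up to 9 and 14. The latter designs have too few splits for a share under 0.05. For preeclamptic debris in 10 arrays, list calls at the preset correlation may come from genes that vary together between any arrays, as in 32 and 35 of the 35 splits. The list calls of normotensive debris were not set apart by the regrouping either, since 7 of 10 splits called as many as the real 3. Among the other splits that part all 3 numbers, those with 4 and 3 lists also reached the real 3.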

How the results depend on the processing

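The tests on the 9 arrays without preeclamptic debris replicate 2 and on the 7 arrays of numbers 1 and 3, with every alternative applied to the 9 arrays, were chosen only after the result was seen.

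The counts of genes depended on the settings more than any other result. Between preeclamptic and normotensive debris in 10 arrays, 0 genes were higher and 5 lower. The lower count became 0 with quantile normalization, centring on the median, the mean of all probe sets, without probe sets ending in _x_at or _s_at, without genes under the 40th percentile, with trend and robust moderation, with a replicate block, with replicates 1-1 and 1-2 averaged and with only the arrays of the 2 groups. Array weights gave 1010 higher and 1548 lower, numbers 1 and 3 gave 181 and 388, and all probe sets tested one by one gave 1 higher. Leaving out 1 array gave 0 to 132 higher and 0 to 387 lower. The weight of preeclamptic debris replicate 2 was 0.0421 where the others had 0.318 to 3.88, so the weighted fit nearly leaves that array out by construction.

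Against untreated cells in 10 arrays, 0 genes were higher and 5 lower. The lower count became 0 with quantile normalization, centring, trend and robust moderation, a replicate block, averaging of replicates 1-1 and 1-2 and only the arrays of the 2 groups. It became 3 with the mean of all probe sets, 2 without suffixed probe sets, 2 without dim genes and 16 with all probe sets one by one, which also gave 1 higher. Array weights gave 1263 higher and 1872 lower, and numbers 1 and 3 gave 247 and 740. Leaving out 1 array gave 0 to 211 higher and 0 to 823 lower. Normotensive debris against untreated cells gave 0 genes in every setting, so the overlap of the comparisons with untreated cells was 0 in every setting by construction.

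In the 9 arrays, 132 genes were higher and 387 lower between the debris groups. Quantile normalization gave 203 higher, the replicate block 388 and 759, the random replicate block 307 and 696, array weights 997 and 1611 and all probe sets one by one 356 and 669. Averaging replicates 1-1 and 1-2 gave 5 and 18, and only the arrays of the 2 groups gave 38 and 156. Leaving out 1 array gave 4 to 265 higher and 16 to 793 lower. Against untreated cells 211 were higher and 823 lower. The replicate block gave 402 higher, the random block 444, array weights 1275 and 1985, all probe sets one by one 518 and 1248, averaging 12 and 71 and only the arrays of the 2 groups 94 and 484. With 1 array left out there were 10 to 304 higher and 53 to 1100 lower. Averaging and leaving out groups lower the degrees of freedom by construction, and the cause of the other changes was not tested.

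The preeclamptic debris arrays did not meet the limit for pairing with the other groups by number, and the block is given for them only here. Their deviations correlated with those of untreated arrays of the same number at 0.0115, 9.27e-05, −0.0155 and 0.0398 across genes, and with those of normotensive debris arrays at −0.0404, 0.0866, −0.0782 and −0.0213, all under 0.1. With replicate 2 left out of the group mean, replicate 1-2 with normotensive debris 1 reached 0.252 and replicate 3 with normotensive debris 3 reached 0.124, but replicate 1-1 correlated better with normotensive debris 2 (0.102) than with 1 (−0.0332), and no pair with untreated cells passed 0.0933. Some pairing of the preeclamptic debris arrays is therefore not ruled out. With the replicate block in the 9 arrays, between the debris groups interferon (2.44e-11), NF-kappaB (4.9e-04), chemokines (0.00269) and the unfolded protein response (8.82e-05) passed and endothelial identity did not (0.199). Against untreated cells the unfolded protein response (7.13e-05) and NRF2 (0.0237) passed. In 10 arrays the block made chemokines pass between the debris groups (0.00173). For normotensive debris against untreated cells it changed no call beyond the erythroid and fibroblast lists given in the report.

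The numbers of lists past the threshold in 10 arrays were 6 between the debris groups, 5 for preeclamptic debris against untreated cells and 3 for normotensive debris. An estimated correlation and fry gave 0 in each. Numbers 1 and 3 gave 3 for preeclamptic debris against untreated cells. For normotensive debris the mean of all probe sets gave 5, leaving out dim genes 7 and numbers 1 and 3 gave 6. With 1 array left out there were 1 to 9, 3 to 7 and 2 to 9 lists. Of the list results in 10 arrays, 283 settings gave the same call, 61 a weaker one, 19 a stronger one and 11 a reversed direction, and in the 9 arrays 262, 38, 46 and 6.

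Several list calls were lost with the processing, and the cause was not tested. Between the debris groups in 10 arrays, leukocytes were lost with quantile normalization (0.166), and leaving out dim genes ended the calls of leukocytes (0.33), syncytiotrophoblast (0.116), interferon (0.111) and NF-kappaB (0.0515). Against untreated cells erythroid genes were lost with quantile normalization (0.18), the mean of all probe sets (0.0821) and without dim genes (0.195), and leukocytes with quantile normalization (0.197) and without dim genes (0.178). Endothelial identity was lost between the debris groups in the 9 arrays without dim genes (0.0637). The syncytiotrophoblast and cell cycle calls against untreated cells in the 9 arrays ended with quantile normalization (0.0532 each) and without dim genes (0.164 and 0.2). The erythroid call for normotensive debris in the 9 arrays ended with quantile normalization (0.081) and without dim genes (0.0549). Numbers 1 and 3 alone lost the endothelial (0.268 and 0.0741) and syncytiotrophoblast (0.103 and 0.0617) calls of both comparisons with preeclamptic debris.

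Some lists changed direction when 1 array was left out, and their adjusted p ranged widely. Between the debris groups the interferon list ranged from 2.85e-11 to 0.791 and the unfolded protein response from 0.0915 to 0.982 in 10 arrays, and in the 9 arrays interferon ranged from 3.27e-08 to 0.458 and chemokines from 0.0196 to 0.73. Between normotensive debris and untreated cells in 10 arrays, interferon ranged from 2.32e-26 to 0.975, fibroblasts from 0.12 to 0.989, the unfolded protein response from 7.72e-08 to 0.809 and p53 targets from 7.71e-05 to 0.987. In the 9 arrays the unfolded protein response ranged from 9.05e-08 to 0.907 and p53 targets from 2.64e-06 to 0.907. Many of these ends come from leaving out an array of number 2 or normotensive debris replicate 1.

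Directions of the genes always given also turned, none of them past the threshold in the 10 arrays. Between the debris groups FLT1 became 0.42 with array weights and 0.28 in numbers 1 and 3, PGF became 0.0433 in numbers 1 and 3, and NOS3 and SELE became −0.0207 and −0.0713 with the mean of probe sets. Leaving out 1 array moved VEGFA from −0.0498 to 0.37 and ICAM1 from −1.004 to 0.22. Against untreated cells FLT1 became 0.15 with weights and 0.0224 in numbers 1 and 3, PGF 0.10 and 0.14, and CXCL8 0.43 and 0.56. IL6 became −0.0881 with a block, −0.23 with weights and −0.12 in numbers 1 and 3, and ICAM1 became −0.0621 with the mean of probe sets and −0.0446 with averaging. Without 1 array or another, PGF moved from −0.62 to 0.0372, VEGFA from −0.0152 to 0.41, ICAM1 from −0.25 to 0.96, IL6 from −0.15 to 0.23 and CXCL8 from −2.005 to 0.80.

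For normotensive debris against untreated cells, ENG became 0.0669 with weights, and PGF became 0.0103 with centring, 0.13 with weights and 0.10 in numbers 1 and 3. The removal of 1 array moved FLT1 from −0.76 to 0.24, ENG from −0.48 to 0.39, PGF from −0.30 to 0.38, VEGFA from −0.0676 to 0.22, EDN1 from −0.93 to 0.56, VCAM1 from −0.0854 to 0.84 and HMOX1 from −0.0242 to 0.19. The ends again fell mostly on untreated or normotensive debris replicate 2.

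Of the genes named from the 9 arrays, the values of KLF3, PSPC1 and JADE2 turned to 0.23, 0.21 and 0.25 against normotensive debris and to 0.20, 0.0546 and 0.30 against untreated cells without probe sets ending in _x_at or _s_at, which is by construction a change to 1 other probe set. A further probe set of JADE2 without these endings fell by 1.28 and 1.23 and passed in both comparisons, so its fall did not turn on every remaining probe set, and a further one of KLF3 was at 2.42 and 2.49. With the same setting NEDD9 and ARRDC3 shrank to −0.2711 and 0.5987 against normotensive debris and BTRC to −0.2617 and −0.2455 in the 2 comparisons, none of them past the threshold. No other named gene reversed, and 830 of the gene results in the 9 arrays were the same, with 210 weaker. The results are limited by the number of arrays, with 3 or 4 per group, and by genes whose signal lies near the background.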

Other observations

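The tests of gene families among the calls in this part were chosen only after the result was seen, with families put together from gene symbols once the calls were known.

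Zinc finger genes with ZNF symbols were common among the falls with preeclamptic debris. In the 9 arrays 45 of 491 such genes, or 9.16%, fell against untreated cells, compared with 4.42% of other genes, and ZNF594, ZNF652, ZNF827 and ZNF37A led them. Most of these encode DNA-binding repressors of transcription. Among the rises they made up 0.611% of members against 1.18% of other genes. In numbers 1 and 3 the falls were 8.15% against 3.97%, and between the debris groups 3.46% against 2.1% (adjusted p 0.0801).

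Splicing factor genes were common on both sides. Of 120 genes, 12 or 10% fell against untreated cells, compared with 4.51% of others, among them RBM45, RBM12, SF1 and SRSF3. A further 6, or 5% against 1.14%, rose, among them the splicing kinase gene CLK3, RBM25, RBM18 and SNRNP27. Between the debris groups in the 9 arrays the falls were 5.83% against 2.11% (adjusted p 0.0292, Fisher's exact test). The rises there were 5.83% against 0.695% (0.000203). In numbers 1 and 3 the falls against untreated cells were 7.5% against 4.06% and did not pass (adjusted p 0.0853). Those between the debris groups did not pass there either (0.0791), while the rises passed in both comparisons (0.00419 each).

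Some single genes of lists that did not pass were called in the 9 arrays. The ligase gene MDM2 and the p53-induced TIGAR fell by 0.85 (SE 0.149) and 0.81 (SE 0.17) against normotensive debris, and MYC and FOSL2 fell by 1.24 (SE 0.256) and 1.52 (SE 0.262), while the sterol oxidase gene MSMO1 rose by 0.83 (SE 0.184).

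Hypothesis 1 was that ZNF genes fall together with preeclamptic debris. It was tested by Fisher's exact test on the falls against untreated cells in the 9 arrays, and the adjusted p was 0.000127, with 0.478 for the rises, but the family was put together once the calls were known. The test therefore only restates the counts above and does not bear the hypothesis out, for which other samples would be needed.

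Hypothesis 2 was that splicing factor genes fall together. The adjusted p was 0.0279 for the falls and 0.00755 for the rises, so a fall in one direction was not borne out.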
